A study of Mus musculus with 4 samples.

How the data were processed

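RNA was measured in 4 samples of Mus musculus, 2 of lineage-negative CD44+ and 2 of lineage-negative CD44- cells sorted from gastric tumours. Per the labels' protocols, 25 ng of total RNA per sample was amplified and 0.2 ug of the amplified RNA was labelled with Cy3, so each array holds 1 sample and 1 colour. Amplification from little RNA can distort the ratio between transcripts and lose rare ones. Groups and replicate numbers were taken from the sample titles.

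The authors deposited 1 scanner table per array and 1 table of processed values. Per the file headers, the scanner tables were written by Agilent Feature Extraction 10.1.1.1, while the submitters' processing notes name version 9.5. Which version made the values is not settled here. The processed signal in them is an intensity on a linear scale after background subtraction, per the file headers, with all values above 0 and no scaling between arrays. The median spot signal and median local background are raw intensities, per the file headers. The other columns used were 0 or 1 flags that the authors' software set for outlier spots, saturation and signal well above background. The authors' value table has no description in the labels. Set against the scanner values, it holds a linear ratio: each array divided by 1 factor, each probe divided by its median over the 4 arrays, and low values held at 0.01. For 10728 probes with a processed signal above 200 on all arrays, log2 differences between arrays matched those of the processed signal up to 1 constant per array, with an SD of at most 0.00161, and each of these probes had a median of 1 within 0.001. Direction, centring and linear scale are therefore known, and how the factors were chosen is not. The medians of its columns are 0.853 and 0.989 for the CD44+ replicates and 0.928 and 0.739 for the CD44- replicates.

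Each array held 43379 spots of gene probes among 45018 spots. Control spots and spots flagged as outliers (109 to 133 per array) were left out, and spots of the same probe were averaged, which gave 41174 probes. The values analysed were log2 of the processed signal minus the array's 75th percentile. Gene names came from matching the accession of each probe, without version, to a table of mouse RefSeq genes (GRCm38.p6). This named 24375 probes for 17016 genes, and the remaining 16799 probes kept the accession of the array design. The array design refers to another build, so no coordinates are given. A probe was tested if it was well above background on both arrays of at least 1 group. Each gene was represented by its brightest probe over the 4 arrays, which left 21045 genes, 13411 of them with a symbol. Of the genes picked by the rule for named genes, Muc5ac has a second probe with the opposite sign. Not every gene that the rule picks is reported here.

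Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with no covariates. This leaves 2 residual degrees of freedom, to which the variance model added 6.01. P-values were adjusted by Benjamini-Hochberg over all genes tested, and adjusted p values under 0.05 were called. Errors are standard errors of the log2 difference from the fit. Differences are CD44+ minus CD44-. For a gene not well above background on either array of 1 group, with any of its probes, the fold is a lower limit. It sets the mean of the brighter group against, per array, the higher of the gene's own signal and the lowest signal well above background. Gene lists for 33 programmes and cell types were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Lists with at least 3 members tested were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 32 lists tested. The neutrophil list had 2 members tested and was not compared. Of these lists 14 passed, 3 higher and 11 lower in CD44+ cells, and 0 passed with a correlation estimated from the data, where the smallest adjusted p was 0.389. Correlation between genes alone does not explain that loss. With an estimated correlation, camera's test has only the 2 residual degrees of freedom. With a preset one, its degrees of freedom follow the number of genes tested and not of arrays. The estimated correlation reached 0.930 for the mesenchymal transition list. It was 0.00999 for the mast cell list and -0.081 for the mucous neck list, no larger than the preset value. The unadjusted camera p of these 2 lists still rose from 0.000472 to 0.0729 and from 0.000174 to 0.0598. On 2 degrees of freedom few lists could pass, so the loss cannot tell whether the calls hold.

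The genes named were Cd44 and the transgene genes, up to 12 per direction with the largest change among called genes well above background on all 4 arrays without overlap of the groups, up to 5 per direction with the largest lower limit, up to 4 members per list with the smallest adjusted p, and Slc7a11, Lgr5, Axin2, Epcam, Ptprc, Pecam1 and Mki67 whatever their value. Where a name outside this rule is given, the text says that it was chosen after its value was seen. Genes known only by an accession or a predicted number were skipped.

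The fit was tested on simulated data for the CD44+ and CD44- comparison, with 200 genes changed by known amounts among 21045, 50 of each size. It called 0% of changes of 1 on the log2 scale, 8% of those of 2, 84% of those of 4 and 100% of those of 6. Of 20801 unchanged genes 9 were called. Camera called both of 2 shifted lists in the right direction and 0 of 30 others. The simulated noise was normal, equal in both groups, and had variances drawn from the fitted variance model. The shares called therefore hold only as far as that model does. Noise was drawn for each gene apart, so it held no correlation between genes. In the real data the estimated correlation was 0.827 for the fibroblast and 0.915 for the endothelial list, though 0.00999 for the mast cell list. The simulation therefore cannot show how often camera calls lists of correlated genes falsely. Changes of 4-fold or less are thus mostly missed in a comparison of this size.

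The alternatives were median scaling, quantile normalization, another background correction, no filter or a stricter filter on dim probes, the mean of a gene's probes, an intensity trend in the variance, the authors' value table, the replicate number as a block, each array left out in turn, a fold minimum and the estimated correlation for lists. The background alternative (normexp, offset 50) was planned on the mean spot signal, a column these files lack. It was run on the median spot signal instead, a choice made after seeing the data. All arrays were on 1 slide with 1 scan date, so neither could be tested as a batch. The alternatives are not independent of one another. Median scaling and the authors' table moved genes by a median of 0.105 and 0.103. The variance model added 3.52 degrees of freedom with quantile normalization, 18.9 with median scaling and 19.2 with the authors' table. With normexp and the replicate block the added number was infinite. Counts of alternatives in which a gene passed therefore describe these fits and are not separate support.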

Results

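The series measured RNA from sorted cells of gastric tumours on 4 one-colour oligonucleotide arrays. The tumours came from K19-Wnt1/C2mE mice aged 30 weeks, in which transgenes make the glandular stomach epithelium express Wnt1 together with Ptgs2 (cyclooxygenase-2) and Ptges (prostaglandin E synthase). The tumours were digested for 3 h, cells carrying lineage markers were excluded, and the rest were parted by CD44, a cell-surface receptor for hyaluronan that has been used to enrich tumour-initiating cells. Which lineage markers were used is not given in the sources used here. The 2 groups were lineage-negative CD44+ cells (2 arrays) and lineage-negative CD44- cells (2 arrays), and the question was which transcripts differ between them.

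The first CD44+ array was the dimmest. Its 75th percentile of processed signal was 257, against 523 on the second CD44+ array and 428 and 575 on the first and second CD44- arrays. Spots well above background made up 53.1%, 65.6%, 66.6% and 69.6% of the gene probes in the same order. No spot was saturated. Over the 21045 genes tested, the 2 CD44+ arrays correlated at 0.965 and the 2 CD44- arrays at 0.947. The first CD44- array correlated at 0.948 with the first and 0.963 with the second CD44+ array. The second CD44- array correlated with them at 0.877 and 0.927. These are correlations across genes, which are not independent replicates. Nothing in the labels says that the replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical. With 2 arrays per group the number of arrays limits the precision of every value.

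CD44+ cells carried less RNA of enteroendocrine and squamous genes than CD44- cells and more RNA of a few genes that included neuropeptide Y (Npy) and the mast cell protease Mcpt1. No gene passed as higher in CD44+ cells with quantile normalization or with no filter on dim probes. Chromogranin B (Chgb), a protein of endocrine secretory granules, was 267-fold lower in CD44+ cells (log2 -8.06 ± 0.48, SE, with 2 arrays per group), and Krtdap, a keratinocyte differentiation gene, was at least 216-fold lower. All 31 cell cycle genes tested had higher signal in CD44+ cells, with a median log2 difference of 1.71, and 25 of them passed when adjusted over the list alone. Fibroblast and endothelial genes were lower in CD44+ cells, with medians of -3.24 and -4.44, and all 14 and 10 of them had at least 2-fold more signal on the second than on the first CD44- array. These list calls used a preset correlation between genes and were lost with one estimated from the data. Camera's adjusted p was then 0.389 for the cell cycle, endocrine and squamous lists and 0.480 for the fibroblast and endothelial lists. For the mast cell and mucous neck lists the same loss came without a larger correlation. With an estimated correlation the test had only 2 residual degrees of freedom, so few lists could pass. The loss therefore does not by itself show that correlated genes made the calls.

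Of the 21045 genes, 84 passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, of which 5 were higher and 79 lower in CD44+ cells. With each array scaled to its median instead, 748 genes passed, 121 higher and 627 lower, which raised the higher share from 5.95% to 16.2%. The authors' value table gave 121 higher and 632 lower. Quantile normalization gave 0 higher and 6 lower, with 78 of the 84 calls lost, and the fit with no filter on dim probes gave 0 higher and 24 lower. At an unadjusted p under 0.05 there were 2263 genes, 601 higher and 1662 lower. At least 2-fold apart without overlap of the groups were 2832 genes, 799 higher and 2033 lower. Groups did not overlap for 39.6% of all genes, where 33.3% do so by chance. The variance model added 5.07 degrees of freedom with either CD44+ array left out and 73.3 with either CD44- array left out, against 6.01 with all arrays. The number of calls changed both with the array left out and with this model. It was 34 without CD44+ replicate 1, 2 without CD44+ replicate 2, 1569 without CD44- replicate 1 and 449 without CD44- replicate 2. The 2 genes left without CD44+ replicate 2 were Krtdap and the ghrelin gene Ghrl, which was singled out after its value was seen.

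Cd44 itself, the sort marker, gave 3.34-fold more signal in CD44+ cells, a log2 difference of 1.74 ± 0.49 (SE, n = 2 arrays per group). The groups did not overlap, at 6.31 and 6.54 against 4.26 and 5.11, in log2 units relative to each array's 75th percentile. The adjusted p of 0.199 did not pass over all genes. The other 2 Cd44 probes pointed the same way, with log2 differences of 1.40 and 2.27. Among the transgene genes, Wnt1 differed by 0.67 ± 0.54 (adjusted p = 0.782) and Ptges by -1.14 ± 0.52 (adjusted p = 0.510). Ptgs2 differed by -4.10 ± 0.89 (adjusted p = 0.124) and was well above background on 1 of the 2 CD44+ arrays. It passed over all genes with median scaling (adjusted p = 0.00281), in the authors' value table and without either CD44- array, and its log2 difference ranged from -5.29 to -2.91 with 1 array left out. Its adjusted p ranged from 2.95e-13 to 0.687 over all alternatives. Whether these probes lie in the transgenes is not known here, so they do not measure transgene expression as such. The 3 transgene genes together did not pass limma's camera (adjusted p = 0.110, or 0.0470 with median scaling), and Ptgs2 alone of them passed when adjusted over the list alone.

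**Figure D1:**
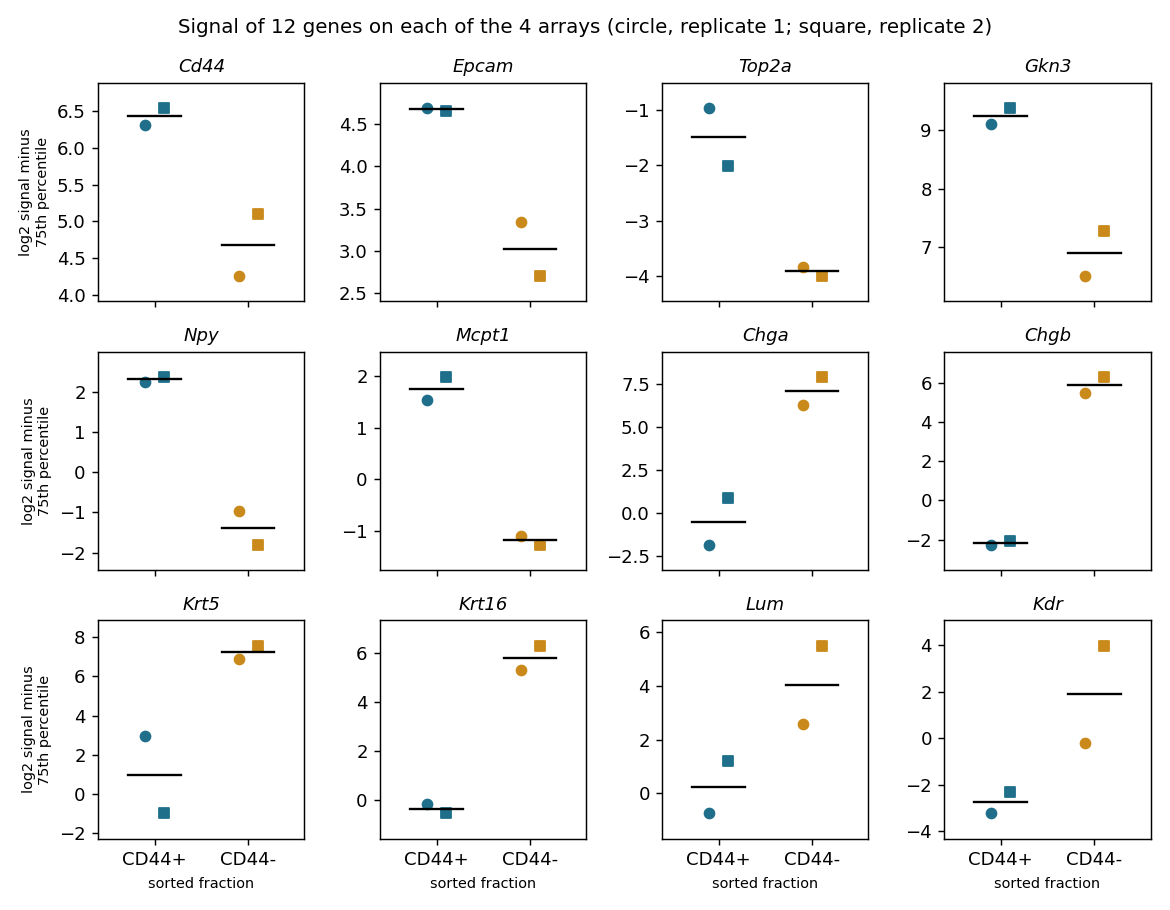
Processed signal of 12 genes on each array, as log2 minus that array's 75th percentile (vertical axes, which differ between genes), for CD44+ and CD44- cells; circles are replicate 1, squares replicate 2 and lines the mean of the 2 arrays. The 2 groups do not overlap for these 12 genes, which the rule that picked some of them required. They do not overlap for 39.6% of all genes tested. The CD44- arrays lie far apart for Kdr, at -0.21 and 3.98.

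Among the genes that passed and were well above background on all 4 arrays, 4 were higher in CD44+ cells. They were Npy, 12.8-fold (log2 3.68 ± 0.48, adjusted p = 0.0270), the secreted phospholipase Pla2g5, 12.1-fold (3.60 ± 0.51, adjusted p = 0.0385), Mcpt1, 7.67-fold (2.94 ± 0.45, adjusted p = 0.0478), and 1 transcript with no gene symbol here. Cd53, a tetraspanin of leukocytes, was at least 9.62-fold higher (adjusted p = 0.0241), since it was not well above background on either CD44- array. On the other side, 24 genes well above background on all 4 arrays were lower in CD44+ cells. The 12 largest falls held endocrine genes, namely Chgb (-8.06 ± 0.48, adjusted p = 0.00174), chromogranin A (Chga, -7.58 ± 0.90), somatostatin (Sst, -6.41 ± 0.65), peptide YY (Pyy, -5.16 ± 0.48) and the serotonin synthesis enzyme Tph1 (-4.77 ± 0.52). They also held the keratins Krt17 (-6.37 ± 0.94) and Krt16 (-6.17 ± 0.51) and the squamous epithelial genes Sprr2d (-5.67 ± 0.48), Lgals7 (-5.54 ± 0.58) and Lypd3 (-5.13 ± 0.53). The acyltransferase Mogat1 (-5.35 ± 0.63) and the niacin receptor Hcar2 (-4.66 ± 0.48) completed the 12. Another 32 of the 84 genes were not well above background in CD44+ cells. Among these, Krtdap was at least 216-fold lower (adjusted p = 0.000716), the endocrine gene Resp18 at least 64.0-fold, Serpinb2 at least 63.5-fold, the pancreatic lipase relative Pnliprp1 at least 40.6-fold and pancreatic polypeptide (Ppy) at least 40.3-fold. These lower limits use, for each array, the lowest signal among probes well above background as the floor.

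Leaving out 1 array moved the fold of 10 of the 24 named genes that passed by more than 1.5 times. Resp18, Serpinb2, Ppy and Pnliprp1 were not well above background on either CD44+ array, nor was Cd53 on either CD44- array. Their log2 differences below are fitted against background signal, so the lower limits given above should be read instead. Of the 24, 12 passed without CD44+ replicate 1, Krtdap alone passed without CD44+ replicate 2, and 24 passed without either CD44- array. None of Npy, Pla2g5, Mcpt1 and Cd53 passed with either CD44+ array left out, with quantile normalization or with no filter on dim probes. Without CD44+ replicate 1 and without CD44+ replicate 2, in fits of 3 arrays, their log2 differences were 3.74 and 3.62 for Npy, 3.42 and 3.77 for Pla2g5, 3.17 and 2.71 for Mcpt1, and 3.81 and 3.82 for Cd53. Without CD44+ replicate 1 and without CD44+ replicate 2, the log2 difference was -6.24 and -8.93 for Chga, -7.36 and -5.46 for Sst, -7.95 and -4.79 for Krt17, -7.63 and -6.39 for Resp18, -9.01 and -7.32 for Serpinb2, and -7.70 and -4.62 for Ppy. Without CD44- replicate 1 and without CD44- replicate 2, it was -8.40 and -6.76 for Chga, -6.20 and -4.88 for Lgals7, -4.45 and -6.25 for Mogat1, -7.97 and -5.03 for Pnliprp1, and -4.92 and -3.68 for the Wnt inhibitor Wif1.

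Cell cycle genes were higher in CD44+ cells as a group. None of the 31 passed over all genes, and 25 passed when adjusted over the list alone. Over all genes, Top2a, Aurkb and Cdk1 passed in 5 of 13 alternatives and Bub1 in 4. Topoisomerase Top2a, needed to separate chromosomes, differed by 2.44 ± 0.51 (5.41-fold, adjusted p = 0.00914 over the list alone by limma), and the mitotic kinases Aurkb, Cdk1 and Bub1 by 2.25 ± 0.46, 2.08 ± 0.45 and 2.03 ± 0.44. Limma's camera gave an adjusted p of 4.13e-23, and adjusted p = 0.389 with an estimated correlation. The list median was between 1.62 and 1.84 with each array left out in turn. Mki67 had no named probe and was not analysed here. The median log2 difference of all genes was 0.16, and scaling to the median moved all genes up by 0.11.

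Mucous neck cell and metaplasia genes formed the second group higher in CD44+ cells. All 9 tested lay above 0, with a median of 0.86, and 3 passed over the list alone while none passed over all genes. The 3 were Gkn3 (2.35 ± 0.48, 5.11-fold), the chloride channel Cftr (2.46 ± 0.60) and the water channel Aqp5 (3.08 ± 0.91). With CD44- replicate 1 or 2 left out, the log2 difference was 1.63 and 3.28 for Cftr and 1.81 and 4.35 for Aqp5, and with CD44+ replicate 1 or 2 left out 4.05 and 2.11 for Aqp5. Camera gave an adjusted p of 0.000555, and adjusted p = 0.389 with an estimated correlation. The mast cell list was the third. All 7 members lay above 0, with a median of 1.45, but the groups did not overlap for only 4 of them. The 2 that are not proteases, Kit and Fcer1a, were picked out after their values were seen. Their median was 0.092, below the median of 0.16 of all genes tested. Mcpt1 passed over all genes, though not without either CD44+ array, and 4 passed over the list alone, all of them proteases of mast cell granules: Mcpt1, Mcpt4 (1.97 ± 0.48), Mcpt2 (2.38 ± 0.75) and Cma1 (1.45 ± 0.47). Mcpt2 differed by 3.59 without CD44- replicate 1 and by 1.16 without CD44- replicate 2. A second Mcpt4 probe, well above background on all 4 arrays, differed by 0.88 ± 0.54. Camera gave an adjusted p of 0.00116, and adjusted p = 0.389 with an estimated correlation. The pan-leukocyte list did not pass (median -0.23, adjusted p = 0.231), although Cd53 was higher, and 3 of its 10 members were lower over the list alone.

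Enteroendocrine genes were lower in CD44+ cells. All 13 lay below 0, 11 passed over the list alone and 5 over all genes, these 5 being Chgb, Sst, Tph1, Chga and Ghrl. The median was -2.81, also with 2 genes at their lower limits. Camera gave an adjusted p of 1.15e-18, and adjusted p = 0.389 with an estimated correlation. The median was -3.79 without CD44- replicate 1 and -2.22 without CD44- replicate 2. Squamous genes, which mark the forestomach lining, had 9 of 12 members below 0, and the same number passed over the list alone in that direction. Krtdap passed over all genes. The basal keratins Krt14 (-6.20 ± 1.07), Krt15 (-5.44 ± 0.88) and Krt5 (-6.27) passed over the list alone, and with CD44+ replicate 1 or 2 left out they differed by -8.09 and -4.30 for Krt14, -6.85 and -4.03 for Krt15 and -8.26 and -4.28 for Krt5. Each of these 3 keratins passed over all genes in 9 of 13 alternatives. The cornified envelope gene Ivl, 3.03-fold higher over the list alone and picked out after its value was seen, passed in the other direction. The median was -3.94, or -3.33 with 3 genes at their lower limits, and -4.81 and -3.07 without CD44+ replicates 1 and 2. Camera gave an adjusted p of 8.63e-10, and adjusted p = 0.389 with an estimated correlation. Tuft cell genes had a median of -1.64 (adjusted p = 0.000587 by camera, adjusted p = 0.463 with an estimated correlation). The median was -1.56 with 1 gene at its lower limit, -2.31 without CD44- replicate 1 and -0.97 without CD44- replicate 2. Il25, an alarmin that tuft cells secrete, was at least 2.93-fold lower and passed over all genes (adjusted p = 0.0422). It kept this call in 6 alternatives and lost it in 6, among them the fits without either CD44+ array. The tuft cell kinase Dclk1 differed by -2.37 ± 0.58 and the leukotriene pathway gene Alox5ap by -2.24 ± 0.56, and 4 of the 10 genes passed over the list alone. Dclk1 differed by -3.08 and -1.66 with CD44- replicate 1 or 2 left out.

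**Figure D2:**
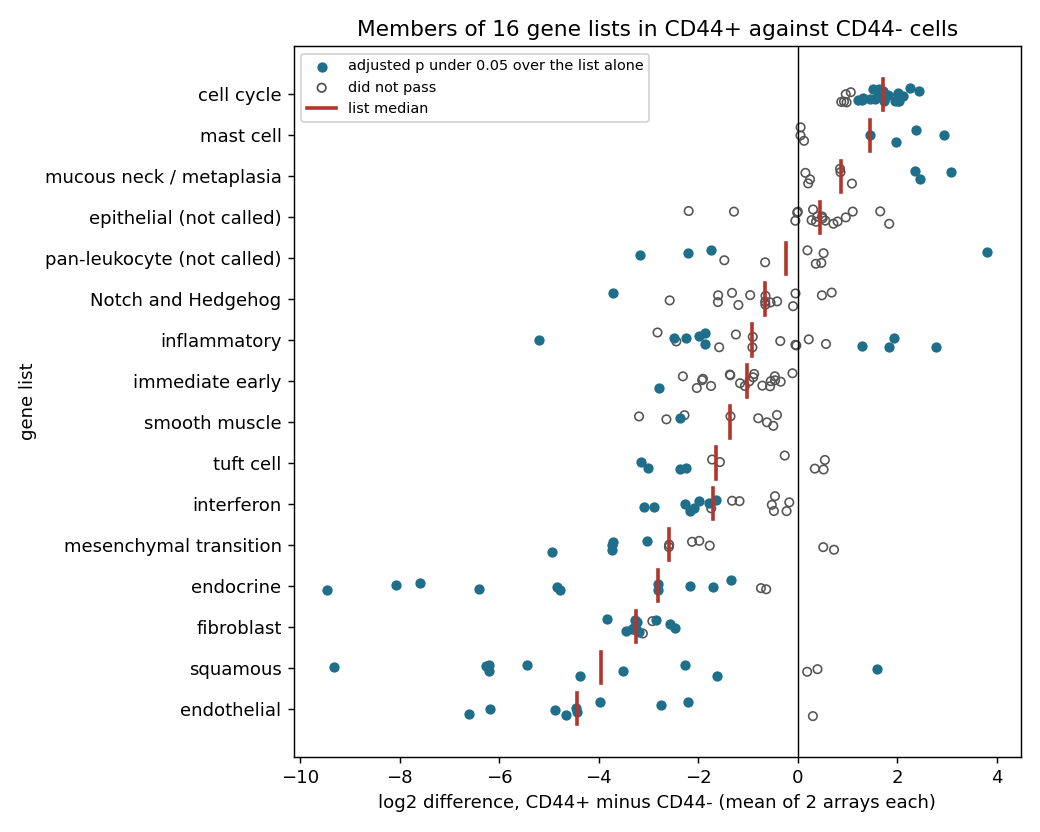
Log2 difference between CD44+ and CD44- cells (horizontal axis) for the members of 16 gene lists (vertical axis), the 14 that passed camera and 2 that did not; filled points passed when adjusted over the list alone, open points did not, and red bars are list medians. Genes not well above background in 1 group are drawn at their fitted values. All cell cycle points lie above 0, and all endocrine and fibroblast points lie below 0.

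Genes of stromal cells were lower in CD44+ cells. Among fibroblast genes all 14 lay below 0 and 12 passed over the list alone, and among endothelial genes 9 of 10 did both. None passed over all genes, though Lum, Kdr and Egfl7 did in 6 of 13 alternatives and Dcn in 5. The proteoglycan Lum differed by -3.83 ± 0.98 (14.2-fold) and Dcn by -3.46 ± 0.97, while Dpt was at least 4.03-fold lower. The vascular endothelial growth factor receptor Kdr differed by -4.66 ± 1.16 (25.2-fold) and Egfl7 by -4.44 ± 1.11. Cdh5, the cadherin of endothelial junctions, differed by -4.45 ± 0.94 and was well above background on 1 of the 2 CD44+ arrays. Camera gave adjusted p values of 2.47e-11 for fibroblast and 3.09e-09 for endothelial genes, and adjusted p = 0.480 with an estimated correlation for both. The fibroblast median level was -3.34 and -0.12 on the first and second CD44+ arrays and -0.49 and 3.16 on the CD44- arrays. The second CD44+ array thus lay above the first CD44- array. Endothelial median levels were -3.01 and -2.20 against -0.13 and 3.48. The second CD44- array carried much of this signal. All 14 fibroblast and all 10 endothelial genes were at least 2-fold higher there than on the first CD44- array. Without it the medians were -1.71 and -2.48, and without CD44- replicate 1 they were -4.75 and -6.26. Without CD44+ replicate 1 and without CD44+ replicate 2 the fibroblast median was -1.97 and -4.50. With 2 genes at their lower limits it was -3.21. Single genes moved likewise with CD44- replicate 1 or 2 left out, to -5.28 and -2.37 for Lum, -4.68 and -2.24 for Dcn, -6.75 and -2.56 for Kdr, -6.46 and -2.41 for Egfl7 and -5.97 and -2.93 for Cdh5, and with CD44+ replicate 1 or 2 left out to -2.86 and -4.80 for Lum, -2.22 and -4.69 for Dcn and -3.76 and -5.15 for Cdh5. Dpt, given as a lower limit, was at -3.72 and -0.97 on the first and second CD44- arrays. Pecam1 was well above background on 1 array and was not tested.

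Further lists moved with these stromal genes. Smooth muscle genes had a median of -1.35 (adjusted p = 0.000275 by camera, adjusted p = 0.480 with an estimated correlation), all 9 lay below 0 and 1 passed over the list alone, the myosin light chain kinase Mylk (-2.37 ± 0.59). Without CD44- replicate 2 the median was -0.48 and the adjusted p 0.0880, and without CD44- replicate 1 the median was -2.29. Mylk then differed by -1.60 and -3.14. The mesenchymal transition list had a median of -2.59 (adjusted p = 1.30e-06, adjusted p = 0.480 with an estimated correlation), with 10 of 12 members below 0 and 5 passing over the list alone. The matrix glycoprotein Sparc differed by -3.73 ± 1.18, and the transcription factor Snai2 by -4.94 ± 0.91, well above background on 1 of the 2 CD44+ arrays. The median was -0.90 without CD44- replicate 2, -4.26 without CD44- replicate 1, -1.81 without CD44+ replicate 1 and -3.41 without CD44+ replicate 2. With CD44- replicate 1 or 2 left out the difference was -5.56 and -1.90 for Sparc and -6.11 and -3.76 for Snai2, and with CD44+ replicate 1 or 2 left out -2.52 and -4.94 for Sparc and -3.84 and -6.03 for Snai2. In the same samples the epithelial list had a median of 0.44, or -0.17 without CD44- replicate 2, and did not pass (adjusted p = 0.116). Its junction gene Cldn7 differed by 1.84 ± 0.44 and the adhesion molecule Epcam by 1.66 ± 0.46 (adjusted p = 0.199). Cldn4 differed by -2.19 ± 0.69 and was well above background on 1 of the 2 CD44+ arrays. With CD44+ replicate 1 or 2 left out Cldn4 differed by -3.15 and -1.24.

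Stress and signalling genes were also lower in CD44+ cells, beside the fibroblast and endothelial medians of -3.24 and -4.44. All 20 immediate early and heat shock genes, which tissue dissociation can induce, lay below 0 (median -1.02, adjusted p = 1.56e-07, adjusted p = 0.480 with an estimated correlation). The heat shock gene Hspb1 (-2.79 ± 0.64) was the 1 that passed over the list alone. The median level of this list was 4.14 on the first and 5.52 on the second CD44- array, relative to the 75th percentile. With CD44- replicate 1 or 2 left out the list median was -1.55 and -0.52, and Hspb1 differed by -3.64 and -1.94. All 16 interferon-stimulated genes lay below 0, with a median of -1.69, or -1.48 with 2 genes at their lower limits. Of these, 8 passed over the list alone, among them the immunoproteasome subunit Psmb9 (-1.65 ± 0.46) and Ifit3 (-3.08 ± 0.61), which was well above background on 1 of the 2 CD44+ arrays (camera adjusted p = 2.33e-08, adjusted p = 0.389 with an estimated correlation). Notch and Hedgehog genes had a median of -0.65 (adjusted p = 0.000911, adjusted p = 0.480 with an estimated correlation), and Gli3 (-3.71 ± 0.65), well above background on 1 of the 2 CD44+ arrays, passed over the list alone. Without CD44- replicate 2 the adjusted p was 0.0740 and Gli3 differed by -2.82, against -4.60 without CD44- replicate 1. Ifit3 differed by -2.34 and -3.83 with CD44+ replicate 1 or 2 left out. No member of these 3 lists passed over all genes.

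Inflammatory genes moved apart. Over the list alone 4 were higher and 6 lower in CD44+ cells, and none passed over all genes. In the alternatives Il33 passed over all genes in 8 of 13, Cxcl5 in 5 of 13 and Cxcl12 in 6 of 12. The alarmin Il33 differed by 2.77 ± 0.44 (6.84-fold, adjusted p = 0.0553 over all genes) and the neutrophil chemokine Cxcl5 by 1.93 ± 0.48. The chemokine Cxcl1 differed by -1.98 ± 0.56, and Cxcl12, a product of stromal cells, by -5.20 ± 1.23 with 1 of the 2 CD44+ arrays well above background. With CD44- replicate 1 or 2 left out they differed by -2.70 and -1.27 for Cxcl1 and -7.22 and -3.19 for Cxcl12, and with CD44+ replicate 1 or 2 left out Cxcl12 differed by -4.09 and -6.31. The list passed camera as lower (median -0.91, adjusted p = 0.0400), with adjusted p = 0.681 with an estimated correlation. The adjusted p was 0.191 without CD44+ replicate 1, 0.722 without CD44- replicate 2 and 0.275 on genes well above background on all 4 arrays. The median was -1.65 without CD44- replicate 1 and -0.16 without CD44- replicate 2.

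Wnt target and stem cell genes did not pass as groups. Among 21 Wnt targets 14 lay above 0 (median 0.39, camera adjusted p = 0.674). The list's mean was below 0 at -0.14 because of a few large negative values, among them Wif1 and Dkk2. Dkk2 was not well above background on either CD44+ array. The list passed as higher only on genes well above background on all 4 arrays, a filter that removes Wif1, Dkk2 and Rspo1. Wif1 was lower (-4.30 ± 0.55, adjusted p = 0.0251) and was well above background on 1 of the 2 CD44+ arrays. It was the 1 target that passed, over all genes and over the list alone, and it did not pass without either CD44+ array. The targets Axin2 (1.28 ± 0.46, adjusted p = 0.330) and Sp5 (1.90 ± 0.57, adjusted p = 0.236) did not pass. The intestinal stem cell gene Lgr5 differed by -0.070 ± 0.78, a value that turned positive with median scaling, in the authors' table, without CD44+ replicate 2 and without CD44- replicate 2. None of 18 stem and progenitor genes passed over either set (median 0.23, adjusted p = 0.195); Prom1 differed by 1.59 ± 0.44 and Lrig1 by 1.19 ± 0.47. Glutathione and antioxidant genes had 12 members above and 12 below 0 (median 0.057, or -0.12 with quantile normalization, adjusted p = 0.777), and none passed over either set. The cystine transporter gene Slc7a11, which CD44 variants help to hold at the cell surface, was not well above background in CD44+ cells and was at least 1.04-fold lower (adjusted p = 0.423). The extracellular peroxidase Gpx3 differed by -3.72 ± 0.97 (adjusted p = 0.178) and was well above background on 1 of the 2 CD44+ arrays. With CD44+ replicate 1 or 2 left out Gpx3 differed by -2.32 and -5.11. Catalase (Cat) differed by -1.22 ± 0.47 and Gpx2 by 1.09 ± 0.47. Among 11 prostaglandin genes the prostaglandin transporter Slco2a1 was 18.1-fold lower (-4.18 ± 0.52, adjusted p = 0.0241) and did not pass without either CD44+ array. Over the list alone 3 passed, Slco2a1, Ptgs2 and the constitutive cyclooxygenase Ptgs1 (-3.15 ± 0.95, or -1.86 without CD44+ replicate 1 and -2.03 without CD44- replicate 2), and the list did not pass (median -0.064, which was above 0 with median scaling, quantile normalization and the authors' table; adjusted p = 0.116, or 0.0358 with median scaling).

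The size of the group differences depended on how dim spots were treated. With normexp background correction, chosen after seeing the data, the medians were -1.71 for endocrine, -2.69 for squamous, -0.64 for tuft, -2.13 for fibroblast, -3.11 for endothelial, -0.59 for smooth muscle, -1.24 for mesenchymal transition and -0.60 for interferon genes. On genes well above background on all 4 arrays they were -4.77 for endocrine, -3.33 for squamous, -3.59 for endothelial, -0.79 for smooth muscle, -1.87 for mesenchymal transition, -0.52 for interferon and -0.050 for inflammatory genes. The smooth muscle median was -2.17 with the mean of each gene's probes, and the squamous median -2.89 without a filter on dim probes.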

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

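Normexp on the median spot signal was chosen after seeing the data, and all other alternatives were fixed before the data were examined. Of the values of named genes under alternatives, 1297 kept their direction and side of the threshold, 334 passed newly, in 78 genes, 71 no longer passed and 14, in 8 genes that do not pass, changed sign. The 14 list calls were all kept with median scaling, normexp, no filter, the mean of probes, the intensity trend, the authors' value table, and without CD44+ replicate 2 or CD44- replicate 1. Of them 13 were kept with quantile normalization, on genes above background on all 4 arrays and without CD44+ replicate 1, 11 without CD44- replicate 2 and 0 with an estimated correlation. The test with an estimated correlation had 2 residual degrees of freedom, so it could keep few calls whatever the correlation. Requiring 2-fold changed no count of calls. Slide and scan date as a block were not run, as all arrays shared 1 of each, and the count of 2-fold genes does not depend on the variance model or block. Low signal on the first CD44+ array limits what can be measured at the dim end. Except where fewer genes or arrays were used, the cause was not tested. Values for lists are adjusted p of camera, and for genes log2 differences.

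With median scaling 748 genes passed (121 higher, 627 lower), and the prostaglandin (0.0358), transgene (0.0470), parietal (0.0168) and glial and neuronal (0.0442) lists and Ptgs2 (-3.99) passed. The kinase inhibitor list (0.914) and Lgr5 (0.036) changed direction. With quantile normalization 6 passed (0 higher, 6 lower; 1975 at an unadjusted p under 0.05 by limma), the inflammatory list did not (0.0723), and the glycolysis list (0.660) changed direction. With normexp 540 passed (98 higher, 442 lower), 66 of them among the 84, and 1210 was the number of genes at least 2-fold apart with non-overlapping groups. The prostaglandin (0.000353), transgene (0.0239), surface mucous (0.000187), chief cell (0.000187) and parietal (0.00309) lists, Cd44 (1.69) and Ptgs2 (-2.05) passed. The kinase inhibitor (0.958), glycolysis (0.725) and erythroid (0.983) lists, Alas2 (0.22), Aqp4 (0.038) and Slc7a11 (0.10) changed direction. The other 2 Aqp4 probes tested differed by -3.45 (adjusted p = 0.0234 by limma) and -3.41 (adjusted p = 0.0643), against -0.70 for the brightest one.

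With no filter on dim probes 24 passed (0 higher, 24 lower; 2165 at an unadjusted p under 0.05 by limma) among 32962 genes. The prostaglandin (0.00727), transgene (0.0282), chief cell (0.0138), parietal (0.0159) and glial and neuronal (0.0282) lists passed, and the Wnt target (0.734), glycolysis (0.742), intestinal (0.803), lymphocyte (0.941) and erythroid (0.926) lists changed direction. On genes well above background on all 4 arrays 18 passed as higher and 61 as lower, and 1486 was the number of genes at least 2-fold apart with non-overlapping groups. The Wnt target list (0.00854) passed as higher, under a filter that removes the members Wif1, Dkk2 and Rspo1 because they are dim in CD44+ cells. The inflammatory list (0.275) did not pass, and the hyaluronan (0.147) and glycolysis (0.605) lists changed direction. With the mean of a gene's probes the parietal list passed (0.0329), and the kinase inhibitor list (0.978) changed direction. With an intensity trend 130 genes passed (13 higher), and the kinase inhibitor list (0.963) changed direction.

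From the authors' table of values, 753 genes passed (121 higher, 632 lower), as did the prostaglandin (0.0353), transgene (0.0471), parietal (0.0176) and glial and neuronal (0.0446) lists and Ptgs2 (-3.96), and the kinase inhibitor list (0.868) and Lgr5 (0.034) changed direction. With an estimated correlation the adjusted p was 0.389 for the cell cycle, interferon, neck, endocrine, squamous and mast lists, 0.463 for tuft, 0.480 for mesenchymal transition, immediate early, Notch and Hedgehog, fibroblast, smooth muscle and endothelial, and 0.681 for inflammatory genes.

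The groups share replicate numbers and nothing in the labels pairs them. The differences between replicates 1 and 2 correlated at 0.347 across genes between the groups. With the number as a replicate block 1829 genes passed (336 higher, 1493 lower), as did the prostaglandin (0.00779), transgene (0.0157), chief cell (0.0147) and parietal (0.00134) lists, Cd44 (1.74) and Ptgs2 (-4.10), and the Wnt target (0.787) and kinase inhibitor (0.808) lists changed direction.

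A group left with 1 array is assumed to vary like the other. With each array left out in turn, 2 to 1569 genes passed (0 to 185 higher, 2 to 1384 lower), and 2762 to 5654 was the range for genes at least 2-fold apart with non-overlapping groups. Without CD44+ replicate 1 the count at an unadjusted p under 0.05 by limma was 1142, and without CD44+ replicate 2 it was 2333. The adjusted p ranged from 0.553 to 0.885 for the kinase inhibitor list, 0.0189 to 0.336 for transgene, 1.89e-05 to 0.722 for inflammatory, 0.336 to 0.949 for glycolysis, 0.00101 to 0.830 for macrophage, 0.202 to 0.949 for erythroid and 0.207 to 0.740 for Wnt target genes. It ranged from 0.00510 to 0.917 for glutathione, 0.0134 to 0.181 for prostaglandin, 0.0153 to 0.949 for epithelial, 1.06e-06 to 0.830 for surface mucous, 0.00160 to 0.661 for chief cell, 0.000922 to 0.220 for parietal and 0.00118 to 0.952 for intestinal genes. For glial and neuronal genes it was 0.0166 to 0.339, for Notch and Hedgehog genes 0.000159 to 0.0740 and for smooth muscle genes 1.54e-07 to 0.0880. Log2 differences ranged from -5.29 to -2.91 for Ptgs2, -1.05 to 0.92 for Lgr5, -0.43 to 0.92 for Mpo, -0.69 to 0.20 for Alas2, -2.21 to 0.26 for Guca2a, -5.76 to 0.24 for Chia1 and -3.70 to 0.34 for Pgc.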

Other observations

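All tests of explanations in this part, and the mast cell genes Kit, Fcer1a, Tpsb2, Cpa3 and Ms4a2 named in it, were chosen after the results were seen.

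Genes of differentiated gastric cells went in mixed directions. Among 9 surface mucous cell genes (median 0.36, limma camera adjusted p = 0.50) the surface antigen Psca (-4.55 ± 0.82) and the mucin Muc5ac (-4.65 ± 0.93) passed over the list alone as lower in CD44+ cells. Leaving out CD44- replicate 1 or 2 gave -3.17 and -5.94 for Psca and -3.15 and -6.16 for Muc5ac. A second Muc5ac probe gave 0.22. The trefoil peptide Tff1 differed by 0.56 ± 0.53 and cathepsin E (Ctse) by 1.07 ± 0.59. With CD44- replicate 1 or 2 left out Ctse differed by 1.84 and 0.30. Of 8 parietal cell genes (median -0.58, adjusted p = 0.0752), the proton pump subunit Atp4b (-5.32 ± 1.07) and Kcne2, at least 7.89-fold, passed over the list alone as lower and Kcnq1 (1.32 ± 0.45) as higher. Of 5 chief cell genes (median -1.68, adjusted p = 0.226), the pepsinogen gene Pga5 (-3.05 ± 0.71) passed over the list alone as lower. Among 6 intestinal genes (median 0.10, or -0.13 with quantile normalization, adjusted p = 0.75) Fabp1 (-2.79 ± 0.77) did so. Leaving out CD44- replicate 1 or 2 gave -7.27 and -3.38 for Atp4b, -3.96 and -2.14 for Pga5 and -1.73 and -3.85 for Fabp1. Kcne2, given as a lower limit, was at -2.96 and 0.22 on the first and second CD44- arrays. None of these genes passed over all genes, though Psca did in 8 of 13 alternatives, Muc5ac and Atp4b in 7 each and Pga5 and Fabp1 in 5 each. Glycolysis and hypoxia genes (19 tested, median 0.22, adjusted p = 0.783) had no member that passed over either set, and the glucose transporter Slc2a1 differed by -1.39 ± 0.51. Cyclin-dependent kinase inhibitors and related genes (12 tested, median 0.069, adjusted p = 0.991) had none either, with Rbl1 at 1.51 ± 0.49 and Cdkn1a at -1.05 ± 0.49.

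Among hyaluronan and CD44 partner genes (16 tested, median 0.15, adjusted p = 0.504) the hyaluronan synthase Has2 (-3.48 ± 0.66), well above background on 1 of the 2 CD44+ arrays, and radixin (Rdx), at least 5.69-fold, were lower over the list alone, as was Has3 (-1.85 ± 0.57), again with 1 such array. The CD44 ligand osteopontin (Spp1) was higher over the list alone (1.82 ± 0.54). Leaving out CD44- replicate 1 or 2 gave -4.23 and -2.73 for Has2 and -2.47 and -1.23 for Has3. Leaving out CD44+ replicate 1 or 2 gave 1.18 and 2.45 for Spp1. Rdx, given as a lower limit, was at -3.04 and -0.65 on the first and second CD44- arrays. No member passed over all genes. Among blood cell lists, macrophage genes had a median of -0.42 (10 tested, adjusted p = 0.135), with C1qc at least 1.73-fold lower and the class II gene H2-Ab1 (-1.88 ± 0.50) lower over the list alone. Lymphocyte genes had a median of 0.41 (10 tested, adjusted p = 0.321) and erythroid genes of -0.25 (3 tested, adjusted p = 0.769), with no member passing. The common leukocyte gene Ptprc differed by -0.66 ± 0.47 (adjusted p = 0.765). Of the 2 neutrophil genes measured, S100a9 differed by -3.49 ± 0.71 (adjusted p = 0.111), or by -2.36 and -4.62 with CD44- replicate 1 or 2 left out. Glial and neuronal genes had a median of -0.37 (6 tested, adjusted p = 0.0633), with Uchl1 (-3.34 ± 0.69) and Elavl4 (-2.07 ± 0.49) lower over the list alone, Uchl1 at -4.39 and -2.29 with CD44- replicate 1 or 2 left out. Median, mean and test did not share a sign for 6 lists, namely Wnt targets, cyclin-dependent kinase inhibitors, glutathione, hyaluronan partners, surface mucous and intestinal genes.

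Fibroblast and endothelial genes were lower in CD44+ cells. The endothelial minus the pan-leukocyte median was -4.21 (95% bootstrap interval over genes -5.24 to -1.79), but -2.03 (-3.07 to -0.13) without CD44- replicate 2 and -1.90 (-2.89 to 0.14) without Cd53 as well, so a smaller share of every non-epithelial cell type in the CD44+ sorts stays open. Cells with lineage markers not named here were excluded from both fractions, so the leukocyte list may not follow other non-epithelial cells. Its median level was -2.09 and -2.22 on the CD44+ arrays and -2.16 and -1.92 on the CD44- arrays. Of the 24 fibroblast and endothelial members 23, 95.8%, were at least 2-fold lower in CD44+ cells, which restates the pattern. None of the 24 is on another list, and 13 were well above background on both CD44+ arrays. The fibroblast gene Dcn was at 6.03 ± 1.72 (SD) in CD44- and 2.57 ± 1.75 in CD44+ cells; the share of each cell type in the sorts was not measured, and a biological difference between the fractions stays open, untested.

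Cell cycle genes were higher in CD44+ cells. The cell cycle median exceeded the epithelial median by 1.27 (interval 0.94 to 1.57), by 1.79 (1.21 to 2.03) without CD44- replicate 2 and by 0.85 (0.29 to 1.33) without CD44- replicate 1. Dilution of epithelial RNA by other cells in the CD44- sorts would raise both lists alike. The interval, which resamples genes and not arrays, lay above 0 with all arrays and with each left out. As a set, the cell cycle genes thus rose more than the epithelial genes. The test cannot exclude dilution, since enteroendocrine and squamous cells are epithelial too and their genes were lower in CD44+ cells. Of 18 epithelial genes 14 lay above 0, with Cldn7 at 1.84 and Epcam at 1.66, near the cell cycle median of 1.71. The bound of 0 replaced a bound of 0.5 after these values were seen, and the interval without CD44- replicate 1 reached below 0.5. Dilution, in whole or in part, stays open. The lowest cell cycle median over median, quantile and authors' scaling was 1.66, so the difference held under these scalings. Median scaling and the authors' table moved genes up by a median of 0.105 and 0.103, so these 2 could hardly lower it. None of the scalings can show a difference in total RNA between the fractions. A biological difference between the fractions stays open and was not tested.

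Mast cell protease genes were higher in CD44+ cells. Mast cells among the CD44+ sorted cells could bring these transcripts. The 2 markers tested that are not proteases, Kit and Fcer1a, had a median of 0.092, too few to decide. The mast cell carboxypeptidase Cpa3 was well above background on 1 CD44+ and 1 CD44- array and was not tested, the receptor subunit Ms4a2 was above it on 0 arrays, and the tryptase Tpsb2 differed by 0.055 ± 0.46. The pan-leukocyte median without Cd53 was -0.66 (interval -2.19 to 0.47), so mast cells and protease expression by other cells cannot be told apart here.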
